A study of Homo sapiens with 4 samples.

How the data were processed

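The series comprised 4 ChIP-seq libraries from A549 lung cancer cells, crosslinked in 1% formaldehyde: anti-Flag, anti-HDAC1 and IgG libraries from cells overexpressing Flag-tagged ZNF296 (ZNF296-OE), and an anti-HDAC1 library from control cells, whose genotype the labels give as wild type. Groups were taken from the labels, with 1 library in each. Per the submitters' processing notes, Trim Galore 0.6.7, Bowtie2 2.4.5, MACS2 2.2.7.1 and the GRCh38 (hg38) build were used. Filters on reads, duplicates and mapping quality are not given in the sources used here. The anti-Flag and both anti-HDAC1 libraries each had a deposited peak list, and the peaks were called per library, with no pooling. The IgG library had no list of its own and entered through the calls. Which IgG library served the HDAC1 control list is not given in the sources used here.

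For each peak the authors' lists give the fold enrichment over IgG at the summit, a ratio computed by MACS2 with a pseudocount of 1. The deposited lists also give the -log10 of the p-value and of the q-value of each peak, and an integer score made by the authors' peak caller from the q-value, which was not used. These are the authors' values, and they served here to describe, rank or filter regions within a list. The alternatives with a minimum fold or q-value set the same minimum in all lists, although the values of different lists are not on the same scale. The lowest -log10 q was 1.32 in the anti-Flag list and 2.42 and 2.43 in the HDAC1 control and ZNF296-OE lists. The lowest fold enrichment was 1.29 in the anti-Flag list and 4.01 in both HDAC1 lists. The HDAC1 lists thus had a higher floor in both values, and which threshold set it was not tested. The HDAC1 lists carry labels that name a fold of 5, but 24.0% of control and 18.8% of ZNF296-OE peaks had fold enrichments under 5, so the lists were not filtered at that value of this column.

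The depth behind each peak was computed from the deposited values. Under MACS2's definitions, the fold enrichment and the Poisson p-value together fix the fragments at the summit and the background expected there. A whole number of fragments that gave the -log10 p-value within 0.01 was found for every anti-Flag peak and for all but 2 HDAC1 control peaks and 3 HDAC1 ZNF296-OE peaks. The lowest common background was taken as genome-wide, and 51.9%, 55.2% and 54.9% of the peaks of the anti-Flag, HDAC1 control and HDAC1 ZNF296-OE lists had it. The remaining peaks were called over a local IgG background, which moved in steps of 1 IgG fragment. PCR duplicates may remain among the fragments, so intervals cover counting error only.

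Regions were the peaks on chromosomes 1 to 22, X and Y. The deposited lists also hold peaks on alternate haplotypes, unplaced contigs and the mitochondrial genome, so reads were aligned to these too, and genes with alternate haplotypes can lose regions on the main chromosomes. None overlapped within a list, so none were merged. Regions of different lists were called overlapping when they shared at least 1 bp. A region lay at a gene end when it came within 1 kb of either end of a protein-coding gene in the RefSeq table for GRCh38.p14, which held 20037 such genes. The design had planned distances to transcription start sites, but the table gives no strand and 1 row per gene, so both ends of each gene were used and further start sites were not covered. No genome sequence was used here, so the planned comparison of sequence motifs was not run.

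Percentages carry 95% exact (Clopper-Pearson) binomial intervals. Random overlap was taken from 1000 placements of the regions on their own chromosomes, and again with regions at gene ends placed at random gene ends. HDAC1 regions at ZNF296-Flag were compared with 10000 draws of HDAC1 regions away from it, matched on decile of fold enrichment and on gene-end status. Gene lists were set against 10000 random lists of protein-coding genes of the same size. For ZNF296-Flag this was repeated with the share carrying HDAC1 in control cells matched. With 1 library per group no p-value was computed, and percentiles describe these libraries. There were 21 gene lists, of which 17 were written gene by gene (510 genes, 1 of which matched no protein-coding gene) and the others were families defined by their symbols.

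Genes named in the text were chosen by rule: ZNF296 and HDAC1; the 10 genes with the highest ZNF296-Flag fold enrichment at an end; the 10 with ZNF296-Flag overlapped by HDAC1 in ZNF296-OE cells and no control HDAC1 at that end, by ZNF296-OE fold; up to 5 of the reverse, by control fold; and up to 5 members of each list with ZNF296-Flag. For the 6 immunity lists, up to 3 members with HDAC1 in ZNF296-OE alone and up to 3 in control alone were also taken. The strongest regions inside or between genes, SLC5A11, the region from HLA-F to HLA-DPB1, the tally over the 6 immunity lists and the regions set beside that of CD274 were chosen after their values were seen. The grouping, the gene lists, the overlap and window settings, the naming rule and the alternatives were fixed before the data were examined, apart from alternatives stated as added later.

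Alternatives were windows of 500 bp and 3 kb, the ends of all annotated genes, summits in place of regions, 50% reciprocal overlap, summits within 250 bp, -log10 q of at least 5, fold enrichments of at least 5 or 10, HDAC1 lists of equal length, and the top 10000 regions of each HDAC1 list. Added after the data were seen were a minimum of 10 summit fragments and the use of regions with genome-wide background alone. The computations were tested on simulated data: overlaps equalled a direct search for 100% of intervals, summit fragments were recovered for 100% of simulated peaks, and a planted difference of 20 points between matched groups of simulated regions was returned as 20.2 on average. With no difference planted, 6 of 100 simulations fell outside the 95% range. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.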

Results

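Chromatin immunoprecipitation sequencing was carried out in A549 cells, a human lung cancer cell line of epithelial origin, to map the direct genomic targets of ZNF296 and to ask whether ZNF296 and the NuRD complex act on the same loci. ZNF296 is a zinc finger protein, here overexpressed with a Flag tag (ZNF296-OE cells). HDAC1 is a histone deacetylase and a catalytic subunit of NuRD, the nucleosome remodelling and deacetylase complex. The series held 4 libraries: anti-Flag, anti-HDAC1 and IgG from ZNF296-OE cells, and anti-HDAC1 from control cells. The anti-Flag and both anti-HDAC1 libraries each had a peak list, called by the authors per library over IgG. Each group held 1 library, so no difference reported here has a replicate check, and all intervals cover counting error only.

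The anti-Flag list held 3116 peaks, the HDAC1 list of control cells 25193 and the HDAC1 list of ZNF296-OE cells 28450. On chromosomes 1 to 22, X and Y these came to 3022, 24027 and 27246 regions, covering 1.05, 9.06 and 13.2 Mb, with median widths of 277, 248 and 317 bp. Depth was read back from the peak values. The genome-wide background came to 1.05 fragments per base pair for the anti-Flag comparison, 0.247 for HDAC1 in control cells and 0.308 for HDAC1 in ZNF296-OE cells. The HDAC1 background in ZNF296-OE cells was thus 1.25 times that in control cells, and HDAC1 regions covered 1.46 times as many base pairs. The median summit held 13 fragments in the anti-Flag list, 7 in the HDAC1 control list and 8 in the HDAC1 ZNF296-OE list. Summits under 10 fragments made up 80.7% and 67.0% of the HDAC1 control and ZNF296-OE lists, so most HDAC1 regions rested on few fragments. The IgG step, the weight of 1 IgG fragment over the background, was 0.720 for the anti-Flag list, 0.721 for HDAC1 in ZNF296-OE cells and 0.681 for HDAC1 in control cells. The first 2 lists therefore shared an IgG scale that the control list did not have.

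The first comparison asked where ZNF296-Flag lay on the genome. The series held no anti-Flag library from control cells. ZNF296-Flag regions were thus judged over IgG alone, and signal from the antibody itself could not be told from ZNF296. ZNF296-Flag regions gathered at the ends of genes: 1365 of 3022 regions, or 45.2% (95% exact binomial interval 43.4 to 47.0), lay within 1 kb of an end of a protein-coding gene, against a mean of 3.58% for randomly placed regions of the same widths. A further 28.2% lay inside a gene away from its ends and 26.6% between genes. HDAC1 regions were distributed in much the same way, with 43.1% (42.4 to 43.7) at gene ends in control cells and 48.6% (48.0 to 49.2) in ZNF296-OE cells. In all, 1484 of 20037 protein-coding genes, or 7.41%, carried a ZNF296-Flag region at an end. The gene table used here gives no strand, so gene starts and gene ends were not told apart.

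The strongest ZNF296-Flag regions, ranked by the authors' fold enrichment, included regions inside genes, between genes and at gene ends. The highest lay inside ADGRD1, an adhesion G protein-coupled receptor gene (chromosome 12, 131045659 to 131047644, GRCh38; 73.0-fold, 149 summit fragments), and overlapped HDAC1 in both lists. The next, on chromosome 15 (92803898 to 92804639; 66.2-fold, 135 summit fragments), lay between genes, 96096 bp from the nearest coding gene end, that of the chromatin remodeller CHD2, and overlapped no HDAC1 region in either list. A region in SERINC2 on chromosome 1 (31431747 to 31432215) reached 57.7-fold. A region inside KRT8, a keratin gene of simple epithelia, on chromosome 12 (52904464 to 52905276) reached 31.2-fold. Both overlapped HDAC1 in both lists.

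Among gene ends, the region with the highest enrichment lay between ZBTB32, a zinc finger repressor gene, and KMT2B, a histone H3 lysine methyltransferase gene (chromosome 19, 35716531 to 35717789; 45.3-fold). It was followed by regions at TP53I3, a p53-inducible oxidoreductase gene (chromosome 2, 24083794 to 24084959; 39.0-fold), and CLCF1, a cytokine gene of the interleukin-6 family (chromosome 11, 67373785 to 67374732; 31.7-fold). Regions at ASB6 (29.7-fold), C19orf33 (27.7-fold) and CTF1, which encodes cardiotrophin 1 of the same cytokine family (27.3-fold), came next. ZNF274, a KRAB zinc finger gene (26.5-fold), RARS1, which encodes arginyl-tRNA synthetase (24.8-fold), and TNFRSF21, a death receptor gene (22.9-fold), completed the 10 genes. Neither ZNF296 nor HDAC1 carried a ZNF296-Flag region at an end. The ends of ZNF296 carried HDAC1 in both lists (10.4-fold in control, 11.4-fold in ZNF296-OE), and the ends of HDAC1 carried a region in the ZNF296-OE list (6.88-fold, 8 summit fragments) and none in the control list.

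The second comparison asked how often ZNF296-Flag regions carried HDAC1, in cells with and without ZNF296 overexpression. HDAC1 lay at most ZNF296-Flag regions in ZNF296-OE cells: 1999 of 3022 regions, or 66.1% (64.4 to 67.8), overlapped an HDAC1 region by at least 1 bp. In control cells the overlap was 1380 regions, or 45.7% (43.9 to 47.5), a difference of 20.5 percentage points. Random regions of the same widths gave means of 1.06% and 0.842%, and random regions with the same share at gene ends gave 7.03% and 4.71%. HDAC1 was in both lists at 1277 ZNF296-Flag regions, in the ZNF296-OE list alone at 722, in the control list alone at 103 and in neither at 920. At gene ends, 86.2% (84.2 to 87.9) of ZNF296-Flag regions overlapped HDAC1 in ZNF296-OE cells and 59.9% (57.2 to 62.5) in control cells, and away from gene ends 49.7% (47.2 to 52.1) and 34.0% (31.7 to 36.3).

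**Figure D1:**
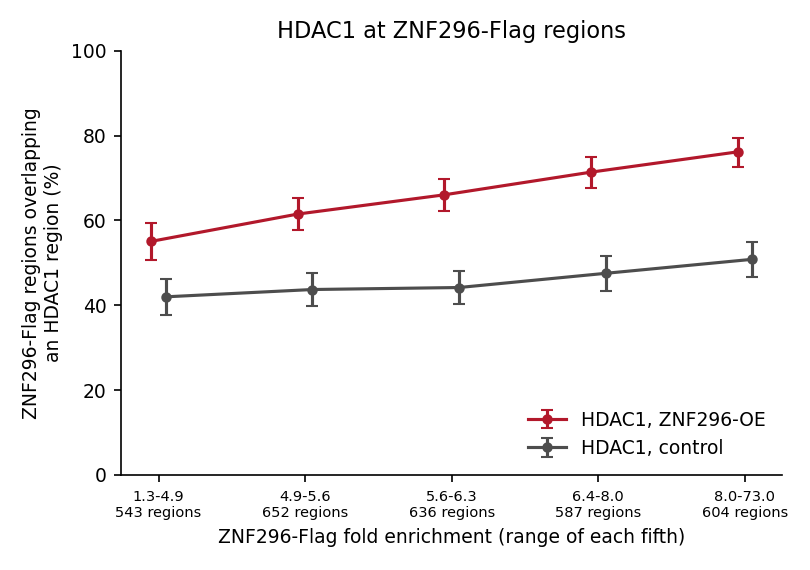
Percent of ZNF296-Flag regions that overlap an HDAC1 region (vertical axis) by quintile of ZNF296-Flag fold enrichment (horizontal axis), for the HDAC1 lists of ZNF296-OE cells (red) and control cells (grey); bars are 95% exact binomial intervals. The share rises from 55.1% to 76.2% in ZNF296-OE cells and from 42.0% to 50.8% in control cells.

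The overlap rose with the strength of ZNF296-Flag. From the lowest to the highest quintile of fold enrichment, the share with HDAC1 went from 55.1% to 76.2% in ZNF296-OE cells and from 42.0% to 50.8% in control cells. Of the 9 regions at the 10 gene ends of highest fold, all overlapped HDAC1 in ZNF296-OE cells, and those at ZNF274 and RARS1 overlapped none in control cells. Where an HDAC1 region overlapped, the summits lay a median of 177 bp apart in ZNF296-OE cells and 173 bp apart in control cells. When an overlap of at least 50% of both regions was asked for, the shares were 17.8% and 12.4%, a difference of 5.43 points. With summits within 250 bp, the difference was 11.9 points. The ZNF296-OE list was also shortened by q-value until it covered no more base pairs away from ZNF296-Flag than the control list. The shares were then 53.9% and 45.7%, a difference of 8.24 points, in a setting chosen after the result was seen. With that list shortened to as many gene-end regions away from ZNF296-Flag as the control list, the difference was 14.3 points. It was larger than reported with -log10 q of at least 5 (26.2 points) or fold enrichment of at least 10 (23.3 points). These minimums cut the control list harder, to 12534 control and 17062 ZNF296-OE HDAC1 regions in the first case and 2347 and 4201 in the second. With HDAC1 lists of equal length the difference was 18.8 points, and with the top 10000 regions of each list it was 16.02 points. With genome-wide background alone, a setting added later, it was 24.3 points.

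By gene, 1179 of the 1484 genes with ZNF296-Flag at an end also carried HDAC1 in both lists. In the ZNF296-OE list alone 246 carried it, in the control list alone 9, and in neither 50. Of all coding genes, 16.1% carried HDAC1 in the ZNF296-OE list alone and 3.34% in the control list alone. The share in the ZNF296-OE list alone was thus near that of all coding genes, and the share in the control list alone was lower. The first does not compare gains, because a gene with control HDAC1 cannot count as ZNF296-OE alone. Most ZNF296-Flag genes had control HDAC1, against 45.6% of all coding genes. Of the ZNF296-Flag genes without it, 246 had HDAC1 in ZNF296-OE cells and 50 did not. Of all 20037 coding genes, 9145 had control HDAC1 and 3229 had HDAC1 in ZNF296-OE cells alone. At 238 genes a ZNF296-Flag region was overlapped by HDAC1 in ZNF296-OE cells with no control HDAC1 region at that gene end. At 6 genes the reverse held. With HDAC1 lists of equal length these counts were 231 and 12. The 238 were led, by fold enrichment of HDAC1 in ZNF296-OE cells, by TRIM65, an E3 ubiquitin ligase gene (17.8-fold), the mRNA export factor gene NXF1 (16.8-fold) and CTF1 (15.3-fold). DGCR8, a microRNA processing gene, and UGDH, a UDP-glucose dehydrogenase gene, followed at 14.5-fold each, then the splicing factor gene SRSF1 (14.1-fold), DENND4C and the myeloid transcription factor gene SPI1 (both 13.0-fold), and DCXR and SLC38A9 (both 12.6-fold). At TRIM65 and CTF1 a control HDAC1 region overlapped the ZNF296-Flag region more than 1 kb from the gene end, and TRIM65, NXF1, SRSF1 and DCXR carried control HDAC1 at the other end. The reverse held at ATG2A, LHX5, SURF1 and RPL7A, which share a ZNF296-Flag region, EIF3J and, named after its values were seen, SLC5A11. EIF3J and SLC5A11 had no ZNF296-OE HDAC1 region at either end.

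The third comparison set the HDAC1 lists of ZNF296-OE and control cells against each other. HDAC1 regions of high enrichment were shared and those of low enrichment mostly were not. Of the ZNF296-OE regions, 12186 of 27246, or 44.7% (44.1 to 45.3), overlapped a control region, and of the control regions 13141 of 24027, or 54.7% (54.1 to 55.3), overlapped a ZNF296-OE region. The median fold enrichment was 8.41 for shared and 5.35 for unshared ZNF296-OE regions, and 6.95 and 5.50 for control regions. Gene ends held 64.4% of shared and 35.9% of unshared ZNF296-OE regions, and 64.1% and 17.7% of control regions. HDAC1 lay at an end of 11704 protein-coding genes in ZNF296-OE cells and of 9145 in control cells, with 8475 in both, 3229 in ZNF296-OE alone and 670 in control alone.

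HDAC1 regions at ZNF296-Flag were shared more often than those elsewhere, in both directions. Absent from the control list were 586 of the 1953 ZNF296-OE regions at ZNF296-Flag (95% interval 28.0% to 32.1%) and 57.2% (56.6 to 57.8) of the 25293 away from it, a difference of -27.2 points. Absent from the ZNF296-OE list were 7.50% (6.16 to 9.03) of the 1360 control regions at ZNF296-Flag and 47.6% (46.9 to 48.2) of those away from it. At gene ends, 97.9% of control HDAC1 regions at ZNF296-Flag were also found in ZNF296-OE cells, against 79.9% of those away from ZNF296-Flag. HDAC1 regions at ZNF296-Flag were stronger and wider: in the ZNF296-OE list their median fold was 9.18 and their median width 767 bp, against 6.12 and 300 bp elsewhere.

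Set against HDAC1 regions of like fold enrichment and gene-end status, the share of ZNF296-OE regions at ZNF296-Flag absent from the control list differed by -2.80 points from that of the matched regions, which was 32.8% (95% range of the difference over 10000 draws -4.45 to -1.13). Control regions at ZNF296-Flag were absent from the ZNF296-OE list in 7.50% of cases, against 26.6% of matched regions (range of the difference -21.0 to -17.2). These ranges describe these libraries and not the conditions. Width was not matched, and wider regions share 1 bp with another list more easily. The unmatched difference changed sign when all lists were limited to regions of at least 10-fold enrichment. There, no control region of that strength was found for 69.3% of ZNF296-OE regions at ZNF296-Flag and 58.6% of those away from it. The difference was 10.7 points. That setting left 292 ZNF296-Flag regions, of which 34.6% overlapped HDAC1 in ZNF296-OE cells. The share at ZNF296-Flag thus rested on few HDAC1 regions, and no interval was computed for the difference.

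**Figure D2:**
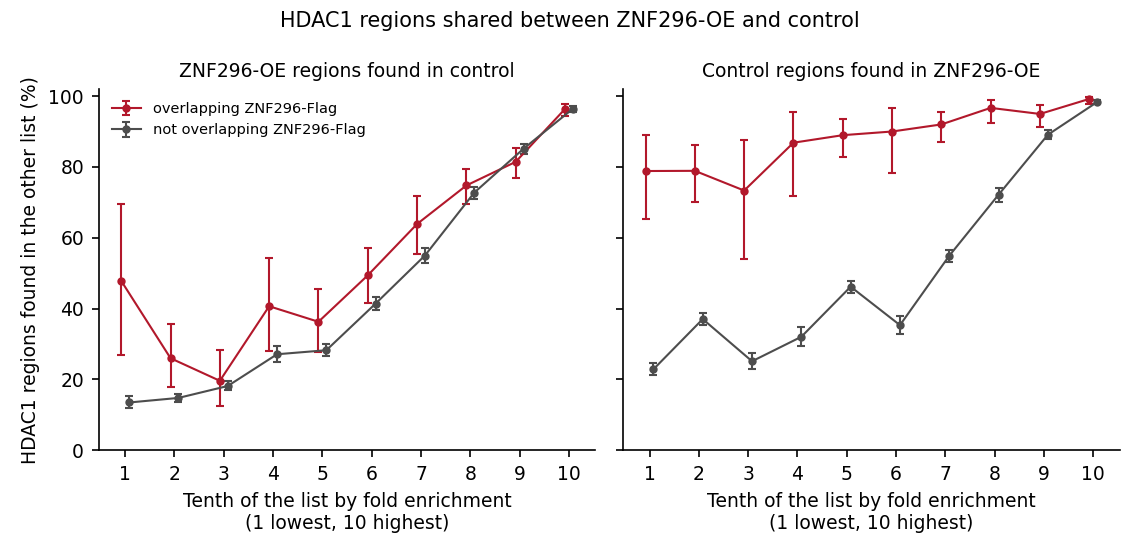
Percent of HDAC1 regions found in the other HDAC1 list (vertical axis) by decile of fold enrichment within the list (horizontal axis), for ZNF296-OE regions (left) and control regions (right), overlapping a ZNF296-Flag region (red) or not (grey); bars are 95% exact binomial intervals. In the highest decile, 96.3% to 99.2% of regions are shared in every group, while in the lowest decile of the control list 78.8% of regions at ZNF296-Flag and 22.9% of the others are shared.

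Over 6 lists of genes of immunity, the subject of the study, 15 of 202 genes carried ZNF296-Flag at an end, beside 7.41% of all coding genes. In the antigen presentation list for MHC class I, 2 of 24 genes carried a ZNF296-Flag region at an end: ERAP1, which encodes the aminopeptidase that trims peptides in the endoplasmic reticulum (10.1-fold), and PSMB10, an immunoproteasome subunit gene (5.96-fold). HDAC1 lay at both genes in both lists, and at ERAP1 the ZNF296-Flag region itself was overlapped in ZNF296-OE cells and not in control cells. The summit of that region lay 189 bp past the upper end of ERAP1 as annotated and 175230 bp from its lower end. Start sites within a gene were not covered, so its distance to other ERAP1 starts is not known. For MHC class II, 0 of 17 genes carried ZNF296-Flag. These counts say little about HLA genes. From HLA-F to HLA-DPB1 on chromosome 6, 0 of 128 coding genes carried ZNF296-Flag, and HDAC1 lay at 7.03% of them in control cells and 10.9% in ZNF296-OE cells, against 45.6% and 58.4% of all coding genes. The deposited HDAC1 lists held 53 and 94 further peaks on the 7 alternate haplotypes of this region, which were left out of all counts by gene, and the ZNF296-Flag list held 0 there. It holds 10 of the 24 class I and 10 of the 17 class II genes. In nucleic acid sensing and type I interferon induction, 2 of 29 genes did: the DNA exonuclease gene TREX1 (9.25-fold), with no HDAC1 in either list, and the RNA sensing adaptor gene MAVS (8.12-fold), with HDAC1 in both. Among interferon receptors, JAK-STAT and interferon-stimulated genes, 4 of 53 did, among them HERC5 (13.1-fold), SOCS3 (7.17-fold) and HERC6 (6.33-fold). HERC5 encodes the ligase that attaches ISG15 to proteins, and SOCS3 a feedback inhibitor of cytokine signalling. HERC6 was the member of this list with ZNF296-Flag and HDAC1 in ZNF296-OE cells but not in control cells.

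Of 43 chemokine and cytokine genes, VEGFA (5.84-fold), CSF1 (4.87-fold) and TGFB1 (4.29-fold) carried ZNF296-Flag, each with HDAC1 in both lists. Of 36 immune checkpoint, adhesion and NK-cell ligand genes, 4 did: PVR, which encodes the TIGIT ligand CD155 (11.2-fold), CD276, which encodes B7-H3 (8.28-fold), CD58 (8.28-fold) and CEACAM1 (7.63-fold). The shares in these 6 lists ran from 0% to 11.1%, and none lay above the 95% range of random lists of the same size. For all but the list of interferon receptors, JAK-STAT and interferon-stimulated genes that range began at 0%, so a depletion was not detectable in lists of this length. In the NF-kappaB pathway, 5 of 26 genes carried ZNF296-Flag: TRAF2 (8.03-fold), NFKBIE (5.84-fold), IKBKG and NFKB2 (4.87-fold each) and RELA (4.85-fold). That share of 19.2% lay at percentile 97.4 of random lists, at 93.3 once matched on control HDAC1 and at 94.5 with a window of 3 kb.

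HDAC1 lay at 61 of the 202 genes of immunity in both lists, at 19 in ZNF296-OE cells alone (9.41%) and at 6 in control cells alone (2.97%). Of all coding genes, 16.1% and 3.34% had HDAC1 in ZNF296-OE cells alone and in control cells alone. The 19 included HERC6 (6.88-fold), PSME2 (10.7-fold) and PDIA3 (6.12-fold) of MHC class I presentation, RFX5 (5.03-fold) of MHC class II, IRF7 (10.7-fold), the antiviral gene OAS3 (8.41-fold), USP18, which encodes the protease that removes ISG15 (7.65-fold), and the neutrophil chemokine genes CXCL5 (9.94-fold), CXCL3 (6.12-fold) and CXCL6 (4.59-fold). Of the 5 such cases among checkpoint and NK-cell ligand genes, ENTPD1 (6.12-fold), CD276 and ULBP1 (5.35-fold each) had the highest fold. The 6 genes with HDAC1 in control cells alone were CD274, which encodes the checkpoint ligand PD-L1 (7 summit fragments), the interferon gamma receptor gene IFNGR1 (8.02-fold), RFXANK (7.22-fold), IFNL2 (5.69-fold), IKBKE (5.62-fold) and DHX58 (4.54-fold). Of the genes named in either direction, HERC6 carried ZNF296-Flag in a region that HDAC1 overlapped, and CD276 in a region that it did not. In the decile of control fold enrichment that holds the CD274 region, 75.7% (71.4 to 79.7) of gene-end regions away from ZNF296-Flag were found in the ZNF296-OE list.

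Lung and foregut genes carried ZNF296-Flag more often than random genes, and epithelial and mesenchymal genes did so in some settings. In the lung and foregut lineage list, 8 of 33 genes, or 24.2% (11.1 to 42.3), carried it, above 99.3% of random lists matched on control HDAC1. HDAC1 lay at 22 of the 33 in control cells and at 19 in ZNF296-OE cells, with 4 in control cells alone. In ZNF296-OE cells alone it lay at 1, or 3.03%, under the random range of 6.06% to 30.3%. That range was not matched on control HDAC1, which lay at 66.7% of this list and 45.6% of all coding genes. A gene with control HDAC1 cannot count as ZNF296-OE alone, so part of the low share was fixed in advance. The 8 genes with ZNF296-Flag were led by those of the transcription factors CEBPB (13.1-fold) and SOX9 (7.91-fold), then the surfactant lipid transporter gene ABCA3 (7.79-fold) and the mucin gene MUC5B (6.82-fold). In the epithelial and mesenchymal list, 7 of 37 genes, or 18.9% (7.96 to 35.2), did, at percentile 98.8. Matched on control HDAC1 the list stood at 98.2, at the upper edge of its range, and with a window of 3 kb at 96.4. These included the keratin genes KRT7 (15.0-fold), KRT18 and KRT8 (a shared region, 10.9-fold), the epithelial factor gene ELF3 (6.75-fold) and VIM, which encodes vimentin (5.56-fold). The region shared by KRT18 and KRT8 was counted for both genes. Counted once, the share of this list would not exceed the upper edge of its random range at 1 kb, 16.2%. Of 24 AP-1 and immediate-early genes, 5 did: DUSP1 (8.34-fold), FOS (6.33-fold), FOSL1 (4.87-fold), ZFP36 (4.55-fold) and DUSP5 (4.38-fold). That list stood at percentile 98.2, and at 91.5 once matched on control HDAC1. With a window of 3 kb it had 8 of 24 genes, or 33.3%, above its random range of 0% to 20.8%. These percentiles describe these libraries, over 21 lists with no correction for their number.

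Other lists stood within the random range or under it at 1 kb. Of the NuRD genes, 1 of 16, CHD3 (9.25-fold), carried ZNF296-Flag, while HDAC1 lay at all 16 in ZNF296-OE cells and at 10 in control cells. The 6 with HDAC1 in ZNF296-OE cells alone, 37.5% of the list, stood at the upper edge of the random range of 0% to 37.5%. Above their ranges stood the ribosomal protein genes, with 21 of 83 in ZNF296-OE cells alone (25.3%, range 8.43% to 24.1%), and ZNF genes, with 112 of 509 (95% interval 18.5% to 25.9%, range 13.0% to 19.3%). Under theirs stood, beside the lung and foregut list, the pluripotency factors (0 of 22) and olfactory receptor genes (4 of 390). At the lower edge of theirs stood nucleic acid sensing (1 of 29) and chemokines and cytokines (3 of 43). None of these ranges was matched on control HDAC1, and a gene with control HDAC1 cannot count as ZNF296-OE alone. Control HDAC1 lay at 32.0% of ZNF genes and 62.7% of ribosomal protein genes, against 45.6% of all coding genes. A low control share, as for ZNF genes, can thus in part place a list above its range, and a high one under it. The ribosomal protein genes stood above their range despite a high control share, so that share does not account for their place. Of those without control HDAC1, 21 had HDAC1 in ZNF296-OE cells and 10 did not. The same holds for the place of the NuRD genes, with control HDAC1 at 62.5%. Of genes of other HDAC1 complexes, 3 of 27 carried ZNF296-Flag: BRMS1 (8.76-fold), SIN3A (5.36-fold) and TRERF1 (4.87-fold). NRF2 target genes had ZNF296-Flag at 4 of 31, UGDH (10.7-fold), OSGIN1 (5.96-fold), SRXN1 (5.93-fold) and TXN (5.56-fold). With a window of 3 kb the NRF2 list had 8 of 31, or 25.8%, above its random range of 0% to 19.4%. Cell cycle genes had 2 of 38, CDKN1C (6.82-fold) and CCND1 (3.66-fold), and pluripotency factors 1 of 22, TFCP2L1 (4.87-fold). Ribosomal protein genes had 7 of 83, led by RPLP2 (12.7-fold), RPL23A (11.9-fold) and RPL26 (9.23-fold), histone genes 3 of 73, H3C15, H3C14 and H2AC19, and ZNF genes 35 of 509. Among genes not expected to be expressed in epithelium, ZNF296-Flag lay at 0 of 390 olfactory receptor genes, 0 of 30 T-cell genes and 1 of 23 myeloid and endothelial genes, SPI1 (14.1-fold). For ZNF296-Flag, the olfactory receptor list alone of all lists stood under the random range of 4.87% to 10.0%.

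**Figure D3:**
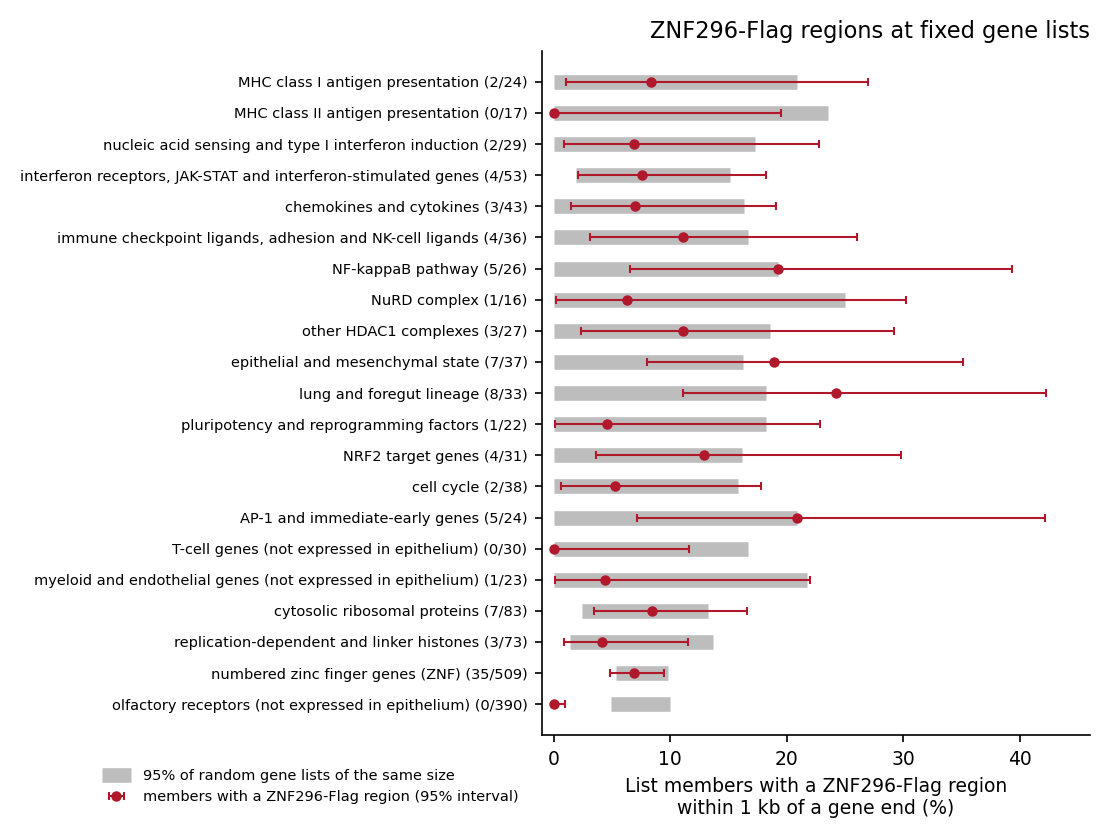
Percent of the members of each of 21 gene lists with a ZNF296-Flag region within 1 kb of a gene end (points, with 95% exact binomial intervals), beside the central 95% of 10000 random lists of protein-coding genes of the same size (grey bars). The lung and foregut list (24.2%) and the epithelial and mesenchymal list (18.9%) lie right of their grey bars, the AP-1 list (20.8%) lies at the edge of its own, and the olfactory receptor list (0%) lies left of its bar. The epithelial and mesenchymal share counts a region shared by KRT18 and KRT8 for both genes.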

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

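The counts in this part were made after the lists were seen, and none was a test. They concern signal on sequences outside chromosomes 1 to 22, X and Y, which no comparison above used and which no IgG peak list was there to gauge. On a pair of unplaced contigs known to carry ribosomal RNA gene repeats, the ZNF296-Flag list held 45 peaks, the HDAC1 control list 38 and the HDAC1 ZNF296-OE list 41. On the mitochondrial genome the lists held 7, 7 and 6 peaks. The median fold enrichment on the contigs was 4.48 in the ZNF296-Flag list, 8.98 in the HDAC1 control list and 6.12 in the HDAC1 ZNF296-OE list. On the mitochondrial genome it was 2.38, 6.55 and 6.28. The median background there, in fragments, was 31.1 in the ZNF296-Flag list against 1.05 genome-wide. All 3 libraries with a list gave peaks on these many-copy sequences, in like numbers but over unlike lengths. In the same order of lists, the contig peaks covered 20401, 96853 and 90244 bp. They made up 1.44%, 0.151% and 0.144% of their lists. Those on the mitochondrial genome covered 2217, 15295 and 13308 bp. No explanation, technical or biological, was tested. The fold enrichments are not on the same scale between lists. Their floors also differ, as the lowest fold was 1.29 in the ZNF296-Flag list and 4.01 in both HDAC1 lists.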

How the results depend on the processing

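Settings with at least 10 summit fragments, or with genome-wide background alone, were added after the data were seen. Of the values that answer a comparison, 55 stayed within their interval or within 1.5 times the reported count. A further 60 moved beyond it and 1 moved to the other sign. Most of the 55 were gene-list values, judged against the wide binomial intervals of mostly short lists, and most of the 60 were not. The NRF2 list, for example, counted as staying when it went from 5.57 to 16.5 points over the random mean within 3 kb. Shares, counts and folds over random placement cannot change sign, so only differences could do so. Among the 55 were 6 differences from the random mean, in 5 gene lists within their random ranges, that changed sign within their intervals. Of the other values, 7 stayed and 24 moved, and all of these are shares or counts, which cannot change sign. Results are given in a fixed order: the share of ZNF296-Flag regions with HDAC1 in ZNF296-OE cells (66.1% as reported) and in control cells (45.7%), their difference (20.5 points), the share of HDAC1 ZNF296-OE regions in the control list (44.7%) and the reverse (54.7%), and the share of HDAC1 ZNF296-OE regions absent from control, at minus away from ZNF296-Flag (-27.2 points).

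With 50% reciprocal overlap they were 17.8%, 12.4%, 5.43 points, 23.1%, 26.2% and -7.36 points. With summits within 250 bp they were 43.1%, 31.2%, 11.9 points, 34.9%, 39.5% and -15.5 points. With -log10 q of at least 5 they were 61.8%, 35.6%, 26.2 points, 46.8%, 66.2% and -13.2 points, and with fold enrichment of at least 10 they were 34.6%, 11.3%, 23.3 points, 41.1%, 74.2% and 10.7 points. With the top 10000 regions of each HDAC1 list they were 47.8%, 31.8%, 16.02 points, 59.7%, 62.8% and -6.74 points. HDAC1 lists of equal length gave 48.98%, 53.3% and -24.3 points for the last 3. At least 10 summit fragments gave 46.5% and 21.4% for the first 2 and -5.25 points for the last. Genome-wide background alone gave 60.1%, 35.8% and 24.3 points for the first 3. Matched regions away from ZNF296-Flag gave -2.80 points for the last. The last of these changed sign at fold enrichment of at least 10, a setting that left 292 ZNF296-Flag, 2347 control and 4201 ZNF296-OE regions. The share at ZNF296-Flag there rested on few HDAC1 regions, and no interval was computed for the difference. The cause of these changes was not tested.

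The overlap over random placement, 62.7-fold and 54.2-fold as reported, was 9.41-fold and 9.69-fold against placements matched on gene ends. The ZNF296-Flag list held 1593 regions at -log10 q of at least 5 and 292 at fold enrichment of at least 10, the HDAC1 control list 12534 and 2347, and the HDAC1 ZNF296-OE list 17062 and 4201. ZNF296-Flag regions at gene ends (45.2%) made up 36.9% within 500 bp, 55.8% within 3 kb, 42.5% at fold enrichment of at least 10, 43.1% with summits in place of regions, and 56.3% with the ends of all annotated genes. At fold enrichment of at least 10, 148 genes carried ZNF296-Flag, 50 with HDAC1 in ZNF296-OE and not in control, and 1 the reverse. HDAC1 lists of equal length gave 12 of the reverse. Against the random mean, the MHC class II, T-cell and olfactory receptor lists stood at -9.26, -9.34 and -9.30 points within 3 kb, and the olfactory receptor list at -2.81 points against lists matched on control HDAC1. Within 3 kb the NRF2 list (percentile 99.6) and the AP-1 list (33.3% of members) lay above their random ranges, and the epithelial and mesenchymal list (percentile 96.4) no longer did.

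With 1 library per group, no difference has a measure of variation between libraries. Summits under 10 fragments in 80.7% and 67.0% of the HDAC1 lists mean that the absence of an HDAC1 region is not evidence of absent HDAC1. The comparison of sequence motifs was not run, as no genome sequence was used here.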

Other observations

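Of the tests in this part, 4 were chosen only after the result was seen: the overlap at equal coverage, the matched comparison of HDAC1 regions of at least 10-fold enrichment, the share of the strongest HDAC1 regions found in the other list, and the comparison of ZNF genes with other bound genes.

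ZNF296-Flag regions overlapped HDAC1 more often in ZNF296-OE than in control cells, and a more sensitive HDAC1 list in ZNF296-OE cells was weighed first. That list was shortened by q-value until it held as many gene-end regions away from ZNF296-Flag as the control list. Then 59.9% and 45.7% of ZNF296-Flag regions overlapped HDAC1, a difference of 14.3 points. This passed the limit set beforehand for sensitivity not being the cause. The cut equalled the number of regions and not their width, so it cannot exclude sensitivity. When the list was shortened further, until it covered no more base pairs away from ZNF296-Flag than the control list, the shares were 53.9% and 45.7%. That difference, 8.24 points, lay between the limits for either outcome. Against placements matched on gene ends the overlap was 9.41-fold in ZNF296-OE cells and 9.69-fold in control cells. Sensitivity may thus account for part of the difference, and whether it accounts for all of it stays open.

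An IgG library shared by the ZNF296-Flag and HDAC1 ZNF296-OE lists stays open too. Where all regions had genome-wide background the difference was 24.3 points, but a shared IgG library would itself decide which regions have that background in both lists, so this value does not argue against it. New HDAC1 at ZNF296-Flag beyond what strength predicts stays open: among HDAC1 ZNF296-OE regions of at least 10-fold, the share absent from control was 6.21% at ZNF296-Flag and 5.65% in matched regions, a difference of 0.565 points (range -1.01 to 2.03). Nearly all regions this strong were in the control list, and recruitment would itself raise the strength they were matched on, so this comparison could hardly have shown a gain. Over all 1953 HDAC1 ZNF296-OE regions at ZNF296-Flag the matched difference was -2.80 points (range -4.45 to -1.13), but control regions at ZNF296-Flag were absent from the ZNF296-OE list less often than matched regions, a difference of -19.1 points (range -21.0 to -17.2). HDAC1 regions at ZNF296-Flag were thus shared more often in both directions, and by more from the control side. Away from gene ends the ZNF296-OE difference was -2.55 points, with a range of -5.11 to 0.135. Width was not matched, and regions at ZNF296-Flag were wider. Their median was 767 against 300 bp in the ZNF296-OE list and 530.5 against 240 bp in the control list. Wider regions share 1 bp more easily, so this sharing cannot be separated from width. Recruitment of HDAC1 by ZNF296 and a difference between single libraries cannot be told apart, because each cell population had 1 HDAC1 library and ZNF296-Flag was mapped in ZNF296-OE cells.

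Over 40% of the regions of each HDAC1 list were absent from the other. Calls near the detection limit of shallow libraries are consistent with this: of the 2723 HDAC1 ZNF296-OE regions in the decile of highest fold enrichment, 96.4% were found in the control list. A different IgG library behind each HDAC1 list could also matter. Regions called over local IgG background were absent from the other list more often than those over genome-wide background in the control list (54.3% against 37.9%, 16.5 points) but not in the ZNF296-OE list (53.9% against 56.4%, -2.50 points), and this stays open because the IgG library of the control list is not given in the sources used here. An effect of ZNF296 overexpression on HDAC1 stays open as well, as it is confounded with the library.

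A hypothesis, raised by the high enrichment at ZNF274, ZNF219, ZNF146, ZNF551 and ZNF672 (26.5-, 20.9-, 20.1-, 19.1- and 15.1-fold), was that ZNF296-Flag is more enriched at ends of ZNF genes than at other bound genes. The median fold of the 35 bound ZNF genes was 7.30, at percentile 98.9 of random draws of bound genes (95% of draws between 5.51 and 7.15). Without those 5 genes the median was 6.82 and the percentile 92.9. The test runs on the genes that raised it and leaves the hypothesis open.

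ZNF296-Flag regions were dense on chromosomes 17, 19 and 16, at 3.74, 3.50 and 2.32 regions per Mb, where coding genes and HDAC1 regions are also dense. A further hypothesis was closeness to chromosome ends. Within 5 Mb of an end lay 24.98% of ZNF296-Flag regions, 18.6% of HDAC1 ZNF296-OE regions and 18.1% of HDAC1 control regions, a difference of 6.42 points between the first 2. This is consistent with some preference for chromosome ends beyond that of HDAC1, in a single library.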
